A study of Mus musculus with 16 samples.

How the data were processed

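The series holds 16 expression arrays of mouse gastrocnemius muscle and C2C12 cells in 3 array sets. The first set has wild-type, mdx, Galgt2 transgenic and Galgt2 transgenic mdx muscle of male mice aged 2 months, 2 arrays each. The second has mdx muscle injected with AAV-Galgt2 and the contralateral muscle injected with PBS, 2 arrays each. The third has C2C12 and C2C12-Galgt2 myoblasts and myotubes, 1 array each. Per the sample labels, 25 ng of RNA was amplified per muscle array of the first set. The labels do not say whether replicates are separate mice, which AAV-Galgt2 and PBS arrays share a mouse, or how the arrays were spread over days, so p-values measure only the spread between these samples.

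The deposited values are intensity per probe set. Per the submitters' processing notes they come from GCOS and RMA, with no versions given, and the notes do not state whether the array sets were processed together. The values are positive and run from 3.9 to 24269, so they were taken as linear and analysed as log2. Array medians lie between 57.69 and 63.95 in the first set, 25.35 and 25.71 in the second and 57.18 and 60.37 in the third, so levels were compared only within a set. Arrays have no read depth. Replicate arrays correlated at r from 0.977 in mdx to 0.993 in AAV-Galgt2 muscle over log2 values of all genes, and the standard deviation of the log2 difference between replicates was 0.607 in mdx, 0.421 in wild type, 0.490 in transgenic, 0.476 in transgenic mdx, 0.334 in AAV-Galgt2 and 0.492 in PBS muscle.

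Probe sets were joined to genes through the supplied probe annotation. Of 45101 probe sets, 34958 carry 1 gene symbol, 932 carry several and 9211 have no listed gene. The last 2 kinds were not used. Symbols were checked by Entrez ID against the supplied gene table, and 0 changed. Each gene was represented by its probe set with the highest mean over the muscle arrays, which gave 18194 genes. For the cell lines the probe set with the highest mean over the cell line arrays was taken instead, so it can differ from that used in muscle, and 1 gene was left out for an empty cell, leaving 18193.

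The 12 muscle arrays were fitted together in limma 3.58.1 (R 4.3.3) with 6 group means, and 6 comparisons were taken: mdx and transgenic against wild type, transgenic mdx against mdx and against wild type, the interaction of transgene and mdx, and AAV-Galgt2 against PBS. P-values were moderated by eBayes and adjusted by Benjamini-Hochberg over all genes within a comparison, two-sided, with 0.05 as the threshold. Counts adjusted over a list alone use the same p-values adjusted within that list.

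A total of 30 gene lists holding 573 genes was fixed before the data were examined, as were the comparisons, thresholds and most alternatives. They cover the dystrophin-glycoprotein complex, laminins with agrin and muscle integrins, the neuromuscular junction, extracellular matrix, macrophages, lymphocytes, neutrophils with mast cells, interferon response, antigen presentation, muscle regeneration, slow and fast fibres, oxidative phosphorylation, glycolysis, lipid use, atrophy, calpains with calcium handling, glycosyltransferases, cell cycle, circadian clock, immediate early and heat shock genes, unfolded protein response, adipocytes, endothelium, smooth muscle, Schwann cells, red blood cells, tendon, skin and ribosomal proteins. Each was tested with limma's camera at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the 30 lists. Named genes are B4galnt2, Dmd and, per comparison, the 10 largest called rises and falls whose replicate values do not overlap between the groups. Where fewer than 5 passed in a direction, the 5 of smallest p were added as not passing. From each list up to 4 called members of largest change were named, or up to 2 of smallest p where none passed. The cell lines followed the same scheme by mean difference, among genes whose higher level is above the median.

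The cell lines have 1 array per condition and were compared without a test, by differences of at least 2-fold and by list medians set against 10000 random lists of matched level. Overlap of comparisons that share arrays was set against 100 simulations with no effect in the second comparison, once with the measured mdx difference and once without it.

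The method was tested on simulated data with the measured spread of each gene, drawn independently for each gene. A log2 change of 2 was recovered in 93% of 100 genes for mdx against wild type and in 93% for AAV-Galgt2 against PBS, a change of 1 in 18% and 21%, with 4 and 5 false calls among 18194 genes. A list of 25 genes shifted by 0.5 was called, and 0 unchanged lists were. Genes of a list vary together in the real arrays, with an estimated correlation of 0.456 for macrophage genes. The simulation lacks this, so it cannot tell how often the preset correlation calls unchanged lists in the real data.

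Alternatives were fits within an array set, the replicate number as a block, quantile normalization over the 12 arrays, arrays shifted to 1 median, the lowest 1 in 3 of genes by level left out, the mean of all probe sets of a gene, limma with a trend, an adjusted p under 0.10, a 2-fold minimum, and each array left out in turn. Chosen after seeing the data were the exchange of the C2C12 labels, leaving out mdx replicate 2 together with transgenic mdx replicate 1, and all list alternatives for transgenic mdx against wild type and for the interaction. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.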

Results

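B4galnt2, the mouse gene also called Galgt2, encodes a glycosyltransferase that adds terminal N-acetylgalactosamine to cell surface glycans. The log2 level of its probe set was 4.61 and 4.94 in the wild-type gastrocnemius arrays, 13.17 and 13.32 in Galgt2 transgenic muscle and 13.28 and 13.34 in Galgt2 transgenic mdx muscle. In the mdx muscle given AAV-Galgt2 it was 10.54 and 10.56, against 5.27 and 4.26 in the PBS-injected muscle. Of the mdx arrays of the transgenic set, replicate 1 had 3.86 and replicate 2 had 7.78. Dmd, the dystrophin gene mutated in mdx mice, had an intensity of 2257 and 2293 in wild type, 367.5 and 281.1 in mdx, 2291 and 2018 in transgenic and 928 and 938.3 in transgenic mdx muscle. Errors are standard errors from limma with 2 arrays per group.

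**Figure D1:**
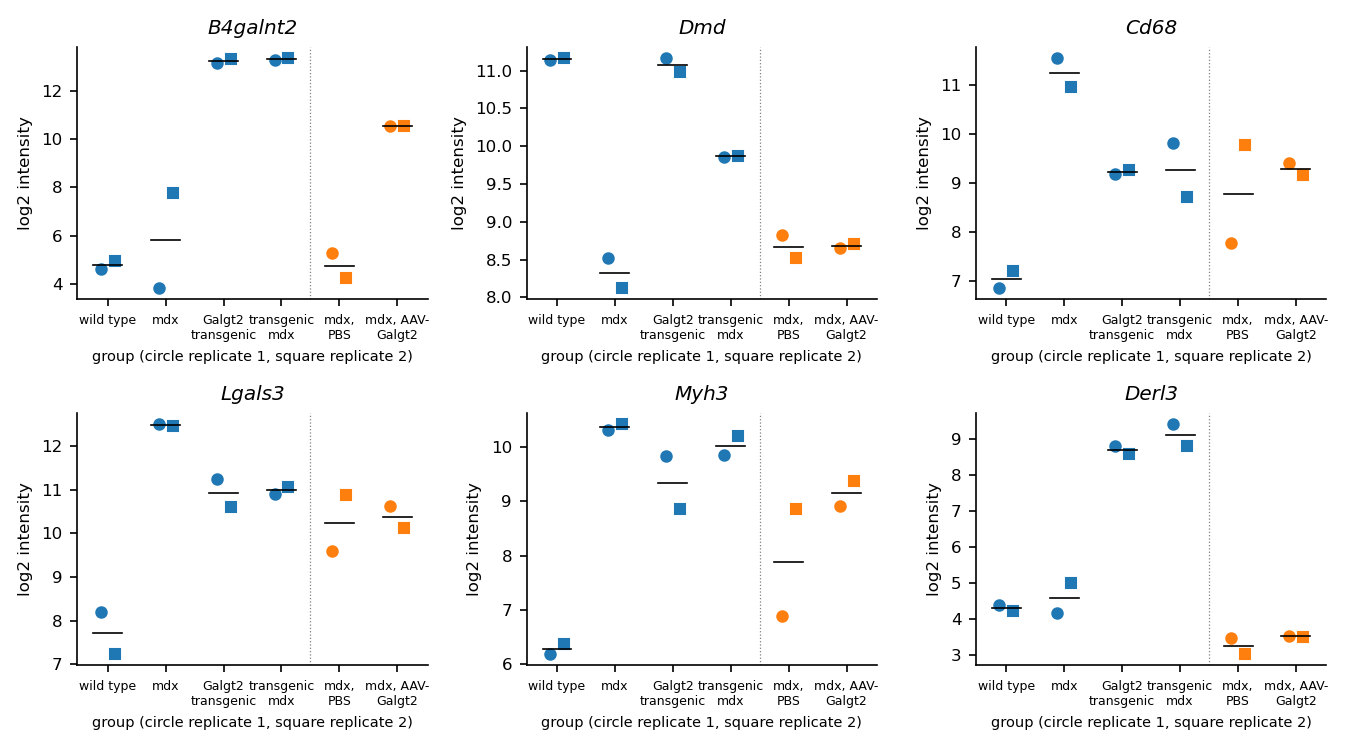
Log2 intensity of 6 genes on the 12 muscle arrays, by group; each point is 1 array, each short line the mean of its 2 arrays, and the dotted line parts 2 array sets whose levels are not on a shared scale. B4galnt2 stands highest in the transgenic and AAV-Galgt2 groups, and Dmd of transgenic mdx muscle lies between mdx and wild type.

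Muscle of mdx mice carried a strong inflammatory and regenerative transcript load. Against wild type, Dmd fell by 2.82 ± 0.20 on the log2 scale (7.08-fold lower, adjusted p = 0.000475), as did Dach2 (-2.98 ± 0.41), a transcription cofactor, and Cdh4 (-2.40 ± 0.29), a cadherin. The macrophage genes Clec4d (5.47 ± 0.77), Lgals3 (4.75 ± 0.43), Gpnmb (4.60 ± 0.56) and Cd68 (4.21 ± 0.56) rose, and Mmp12, a macrophage elastase, had the largest rise at 6.59 ± 1.27. Of 32 macrophage and monocyte genes 26 rose and none fell, 29 when adjusted over the list alone. Their median log2 fold was 2.47 (adjusted p = 8.7e-29, and adjusted p = 0.150 with an estimated correlation). Genes of new muscle fibres rose with them: Mymx, a myoblast fusion factor, by 4.83 ± 0.60, the neonatal and embryonic myosins Myh8 and Myh3 by 4.11 ± 0.40 and 4.10 ± 0.53, and Tnnt2 by 3.82 ± 0.43. In all 12 of 27 regeneration genes rose, 17 over the list alone. The regeneration median was 1.31 (adjusted p = 5.69e-12, and adjusted p = 0.150 with an estimated correlation). Cell cycle genes rose in 13 of 25 cases, 20 over the list alone, with Cks2 at 3.01 ± 0.41. Their median was 1.76 (adjusted p = 7.1e-14, and adjusted p = 0.153 with an estimated correlation).

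Interferon-induced genes were also higher in mdx than in wild-type muscle, 9 of 21 passing and 17 over the list alone. Mx1 (2.88 ± 0.40) and Tap1 (1.83 ± 0.21) rose. The interferon median was 1.06 (adjusted p = 1.8e-12, and adjusted p = 0.153 with an estimated correlation). Antigen presentation genes rose in 8 of 11 cases, 9 over the list alone, with the class II gene H2-Eb1 at 2.07 ± 0.22. The median was 1.44 (adjusted p = 1.81e-10, and adjusted p = 0.150 with an estimated correlation). In the matrix list 9 of 28 genes rose, 16 over the list alone, among them Timp1, an inhibitor of matrix proteases, and Tgfb1 (2.29 ± 0.23). The matrix median was 0.90 (adjusted p = 2.93e-09, and adjusted p = 0.153 with an estimated correlation). The adult fast fibre genes gave no call, with a median of -0.01 and 0 of 16 passing (adjusted p = 0.729).

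In total 990 of 18194 genes differed between mdx and wild type at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 682 higher and 308 lower. With every array shifted to the same median the split was 585 higher and 462 lower, and without mdx replicate 1 it turned to 544 higher and 794 lower. The count was 186 and 132 without wild-type replicate 1 and 2, 495 without mdx replicate 2, and 649 without either AAV-Galgt2 array, which enter through the shared variance. Dmd, Dach2, Cdh4, Clec4d, Lgals3, Gpnmb, Cd68, Mymx, Myh8, Myh3, Tnnt2, Cks2, Mx1, Tap1, H2-Eb1, Timp1 and Tgfb1 passed with each of the 12 arrays left out in turn, and Mmp12 did not without either wild-type array or mdx replicate 1.

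**Figure D2:**
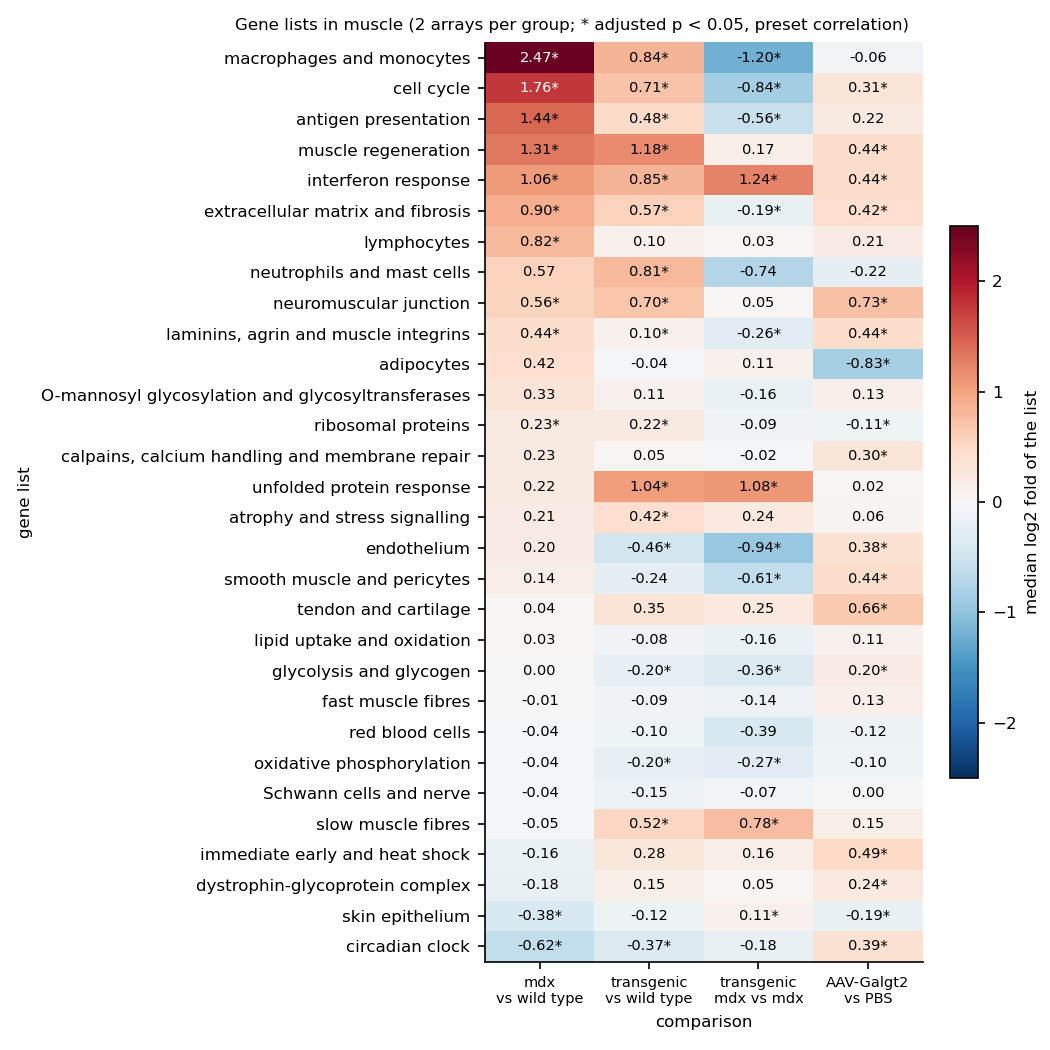
Median log2 fold of 30 gene lists in 4 muscle comparisons of 2 arrays per group; colour and printed value give the median, and a star marks an adjusted p under 0.05 with the preset correlation of 0.01. No starred list passed with an estimated correlation. Macrophage genes have a median of 2.47 in mdx against wild type and -1.20 in transgenic mdx against mdx.

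Galgt2 transgenic muscle without the mdx mutation differed from wild type in 573 genes, 386 higher and 187 lower. B4galnt2 rose by 8.47 ± 0.91 on the log2 scale, while Dmd gave -0.08 ± 0.20 (adjusted p = 0.911). The next largest rises were Gja3 (5.09 ± 0.27), a connexin, Sln (4.95 ± 0.52), the calcium pump regulator sarcolipin, Lce1f (4.95 ± 0.44), a cornified envelope gene, Sox11 (4.93 ± 0.37), a transcription factor, F2 (4.69 ± 0.28), prothrombin, and Derl3 (4.38 ± 0.31), a factor of endoplasmic reticulum protein degradation. Mettl11b (-3.62 ± 0.46), Ppp1r1a (-3.61 ± 0.35), Cdh4 (-3.32 ± 0.29), Dach2 (-3.15 ± 0.41) and Smco1 (-2.99 ± 0.30) had some of the largest falls. All 12 of these genes other than Dmd passed with each array left out in turn.

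Genes of immature muscle were prominent among the rises in transgenic muscle. Of 27 regeneration genes 13 rose and 1 fell, 19 and 1 over the list alone, including Tnnt2 (4.45 ± 0.43) and Myh8 (3.63 ± 0.40). The regeneration median was 1.18 (adjusted p = 6.99e-19, and adjusted p = 0.0987 with an estimated correlation). Chrnd (2.96 ± 0.31), the acetylcholine receptor delta subunit, led a neuromuscular junction list of which 2 of 16 genes rose, 7 over the list alone. The junction median was 0.70 (adjusted p = 1.35e-07, and adjusted p = 0.124 with an estimated correlation). Slow fibre genes rose in 4 of 13 cases, 5 over the list alone, with Tnni1 at 2.25 ± 0.29 and Fhl2 at 2.21 ± 0.24. The slow fibre median was 0.52 (adjusted p = 3.45e-05, and adjusted p = 0.124 with an estimated correlation). Of 20 unfolded protein response genes 7 rose, 14 over the list alone with 1 lower, among them Creld2 (2.44 ± 0.30) and Sdf2l1 (3.20 ± 0.49). Their median was 1.04 (adjusted p = 3.33e-12, and adjusted p = 0.124 with an estimated correlation). The interferon list had 6 of 21 genes up, 13 over the list alone, with the chemokine Cxcl10 at 2.81 ± 0.34. Its median was 0.85 (adjusted p = 1.48e-12, and adjusted p = 0.124 with an estimated correlation). Macrophage genes rose in 4 of 32 cases, 11 over the list alone, with Lgals3 at 3.20 ± 0.43. The macrophage median was 0.84 (adjusted p = 5.78e-10, and adjusted p = 0.240 with an estimated correlation). Endothelial genes were lower as a list, 14 of 14 negative and 0 of 14 passing singly, also over the list alone. The endothelial median was -0.46 (adjusted p = 0.00101, and adjusted p = 0.124 with an estimated correlation), -0.71 without wild-type replicate 1 and -0.33 without wild-type replicate 2.

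The count of 573 was 184 and 193 without wild-type replicate 1 and 2, and 289 and 307 without transgenic replicate 1 and 2, while Sdf2l1 lost its call without wild-type replicate 1 only. The transgenic strain is labelled C57BL/6J like the wild type, mdx C57BL/10J and transgenic mdx a cross of both, so substrain differs between the groups in the other comparisons of this array set.

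In mdx muscle the transgene came with fewer macrophage transcripts and more interferon and unfolded protein response transcripts. Against mdx, transgenic mdx muscle had B4galnt2 higher by 7.49 ± 0.91 and Dmd by 1.54 ± 0.20 (adjusted p = 0.00305). The macrophage genes Gpnmb (-4.15 ± 0.56), Trem2 (-2.87 ± 0.51) and Mmp12 (-6.00 ± 1.27) fell. All 32 macrophage genes were negative, 7 fell, 18 over the list alone, and the median was -1.20 (adjusted p = 3.72e-11, and adjusted p = 0.344 with an estimated correlation), or -0.79 without mdx replicate 1. The lymphocyte list had a median of 0.03 with 0 of 16 passing (adjusted p = 0.907). Cell cycle genes fell in 2 of 25 cases, 8 over the list alone, with the mitotic kinase Aurka at -2.40 ± 0.25. The cell cycle median was -0.84 (adjusted p = 3.08e-07, and adjusted p = 0.344 with an estimated correlation). Endothelial genes fell in 4 of 14 cases, 9 over the list alone, with the junction gene Esam at -1.24 ± 0.22. The endothelial median was -0.94 (adjusted p = 1.73e-07, and adjusted p = 0.123 with an estimated correlation). Gpnmb and Aurka passed with each array left out, Trem2 not without transgenic mdx replicate 2, Esam not without transgenic mdx replicate 2, and Mmp12 not without either transgenic mdx array or mdx replicate 1.

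Rises in transgenic mdx muscle against mdx reached 6.11 ± 0.48 for Dsp, desmoplakin of desmosomes, 6.16 ± 0.74 for Usp17la, 5.88 ± 0.44 for Lce1f, 5.17 ± 0.27 for Gja3, 4.93 ± 0.23 for Muc15, a membrane mucin, and 4.52 ± 0.31 for Derl3. Interferon genes rose in 8 of 21 cases, 12 over the list alone with 3 lower, with Ifit1 at 2.88 ± 0.44 and Cxcl10 at 2.19 ± 0.34. The interferon median was 1.24 (adjusted p = 1.18e-05, and adjusted p = 0.344 with an estimated correlation). Unfolded protein response genes rose in 8 of 20 cases, 12 over the list alone, with Trib3 at 2.86 ± 0.31, Creld2 at 2.32 ± 0.30, the chaperone Hsp90b1 at 1.93 ± 0.32. Their median was 1.08 (adjusted p = 1.73e-07, and adjusted p = 0.344 with an estimated correlation). Slow fibre genes rose in 3 of 13 cases, 6 over the list alone, median 0.78 (adjusted p = 0.000585, and adjusted p = 0.344 with an estimated correlation). Regeneration genes gave no call, with 2 of 27 higher and 1 lower, 6 and 3 over the list alone, and a median of 0.17 (adjusted p = 0.334). Of 12 skin epithelium genes Dsp, Perp (2.68 ± 0.54) and Trp63 (2.60 ± 0.27) rose, 3 also over the list alone, and Perp had no call without mdx replicate 1 (2.49) or 2 (2.88) or transgenic mdx replicate 1 (1.72). The skin median was 0.11 and the mean 0.99 (adjusted p = 0.0388, and adjusted p = 0.344 with an estimated correlation), with no call without mdx replicate 1 (median -0.07) or transgenic mdx replicate 1 (median 0.15), and a median of 0.17 without mdx replicate 2. The cardiac actin gene Actc1 fell by 2.23 ± 0.26. Chrnd rose by 2.08 ± 0.31, the 1 of 16 neuromuscular junction genes that passed, in a list with no call (median 0.05, camera, adjusted p = 0.595).

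The comparison of transgenic mdx with mdx called 1107 genes, 723 higher and 384 lower. The count was 537 without mdx replicate 2, 311 without transgenic mdx replicate 2 and 692 without either AAV-Galgt2 array, and replicate 2 of transgenic mdx had the highest Gapdh 3' to 5' probe set ratio of its array set (log2 1.23 against 0.18 to 0.48).

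Transgenic mdx muscle also stood apart from wild type, with 894 genes higher and 430 lower of 1324 called. Dmd was still lower (-1.29 ± 0.20, adjusted p = 0.00435). Interferon genes rose in 18 of 21 cases, 20 over the list alone, with Mx1 at 4.36 ± 0.40 and Cxcl10 at 3.95 ± 0.34. The interferon median was 2.20 (adjusted p = 9.18e-22, and adjusted p = 0.0914 with an estimated correlation). Regeneration genes rose in 15 of 27 cases with 1 lower, 17 and 1 over the list alone, with Myh8 at 4.66 ± 0.40. Their median was 1.27 (adjusted p = 1.22e-12, and adjusted p = 0.0914 with an estimated correlation). Macrophage genes rose in 12 of 32 cases, 20 over the list alone, with Lgals3 at 3.26 ± 0.43. The macrophage median was 1.37 (adjusted p = 1.16e-10, and adjusted p = 0.252 with an estimated correlation). The count of 1324 was 537 and 434 without wild-type replicate 1 and 2, and 585 without transgenic mdx replicate 2.

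The transgene effect in mdx muscle was compared with that in normal muscle through the interaction of both factors. The interaction takes in the mdx and wild-type arrays with signs opposite to mdx against wild type. Fold changes of both had a Pearson r of -0.859. Of the 682 genes higher in mdx 681 were below 0 in the interaction, and of the 308 lower ones 307 were above 0. The part of the shared arrays in the interaction was not simulated. Lgals3 (-4.70 ± 0.61), Cd84 (-3.13 ± 0.40), Ms4a7 (-2.85 ± 0.36) and Tyrobp (-2.82 ± 0.38), all leukocyte and macrophage genes, had a lower response in mdx muscle. Muc15 (3.21 ± 0.32), AF067061 (2.67 ± 0.26), Tcstv1 (2.47 ± 0.28) and Kcnj3 (2.20 ± 0.29), a potassium channel gene, had a higher one. Among lists, macrophage genes had a median interaction of -1.96 with 2 of 32 lower and 22 over the list alone (adjusted p = 8.82e-25, and adjusted p = 0.153 with an estimated correlation). Regeneration genes had 0 of 27 passing and 11 over the list alone, with a median of -1.24 (adjusted p = 3.34e-13, and adjusted p = 0.125 with an estimated correlation). These 8 genes are all that limma called, beside 2168 at an unadjusted p under 0.05. The count was 0 without wild-type replicate 1 or 2, 142 without mdx replicate 1, 3 and 30 without transgenic replicate 1 and 2, 15 and 3 without transgenic mdx replicate 1 and 2, 2 without either AAV-Galgt2 array and 113 without either PBS array.

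Both effects of the transgene share genes: 184 rose and 65 fell in transgenic against wild type and in transgenic mdx against mdx, and 4 went opposite ways. Independence gives 15.3 and 3.95 in the same direction, and 8.15 and 7.43 in opposite ones. Both comparisons take 1 variance per gene from the same fit, so their calls are not independent and these values are only a rough reference. A shared variance does not by itself favour the same direction. Fold changes of all genes in these comparisons, which share no array, had a Pearson r of 0.391. Of the 682 genes higher in mdx than wild type, 83.0% were below 0 in transgenic mdx against mdx, with 122 called lower and 22 called higher. The measured r was -0.407. The shared mdx arrays alone, simulated with no transgene effect and the whole measured mdx difference taken as real, put 62.6% below 0 and gave an r of -0.221. Simulated with no mdx difference either, they put 100% below 0 and gave an r of -0.501. That 100% covers only simulations in which any gene was falsely called higher in mdx. Both simulations used 1 spread per gene for all groups, while mdx replicates differed most (standard deviation 0.607). The part of the shared arrays may therefore be larger than simulated.

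In mdx muscle injected with AAV-Galgt2, B4galnt2 differed from PBS by 5.78 ± 0.91 and did not pass (adjusted p = 0.233), with an error that takes in its spread between the mdx arrays, while Dmd differed by 0.01 ± 0.20. Without either mdx array of the transgenic set B4galnt2 passed (adjusted p = 0.000142). No gene passed at an adjusted p under 0.05 in limma, and 1506 had an unadjusted p under 0.05. Lists fixed in advance did pass. Neuromuscular junction genes were positive in 16 of 16 cases, 0 passing over all genes and 9 over the list alone, with Lrp4 (0.87 ± 0.21, adjusted p = 0.361), a receptor for agrin, and Ache (1.41 ± 0.35, adjusted p = 0.361), acetylcholinesterase. The junction median was 0.73 (adjusted p = 2.4e-09, and adjusted p = 0.185 with an estimated correlation). Laminin, agrin and integrin genes were positive in 17 of 18 cases, 0 passing over all genes and 6 over the list alone, median 0.44 (adjusted p = 2.78e-08, and adjusted p = 0.128 with an estimated correlation). Matrix genes were positive in 24 of 28 cases, 0 passing and 10 over the list alone, with Col5a1 at 1.61 ± 0.27 (adjusted p = 0.233). The matrix median was 0.42 (adjusted p = 1.06e-06, and adjusted p = 0.274 with an estimated correlation), 0.20 without PBS replicate 1 and 0.72 without PBS replicate 2. Col4a2 (1.56 ± 0.21, adjusted p = 0.178), a basement membrane collagen, Comp (2.03 ± 0.28, adjusted p = 0.178) and the perlecan gene Hspg2 (1.40 ± 0.21, adjusted p = 0.233) had the smallest p-values among the positive genes.

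Tendon genes moved the same way in AAV-Galgt2 muscle, 12 of 13 positive, 0 passing and 3 over the list alone, with a median of 0.66 (adjusted p = 0.000154, and adjusted p = 0.185 with an estimated correlation). Fat cell genes were lower, 8 of 11 negative, 0 passing and 4 over the list alone, with the adipokines Adipoq (-1.53 ± 0.28, adjusted p = 0.233) and Lep (-2.02 ± 0.50, adjusted p = 0.361). The fat cell median was -0.83 (adjusted p = 0.000459, and adjusted p = 0.293 with an estimated correlation), or -0.54 without AAV-Galgt2 replicate 2. Macrophage genes gave no call, with a median of -0.06 (adjusted p = 0.203), and nor did the unfolded protein response (0.02, adjusted p = 0.769). Interferon genes were higher, median 0.44 (camera, adjusted p = 0.0043, and 0.448 with an estimated correlation), or 0.21 without PBS replicate 1. Regeneration genes also had 0.44 (camera, adjusted p = 0.00129, and 0.293 with an estimated correlation), or 0.19 with no call without PBS replicate 1. The control muscle received PBS, so effects of the vector and of Galgt2 cannot be told apart. Leaving out PBS replicate 2 gave 158 called genes, PBS replicate 1 gave 3, and either mdx array of the transgenic set gave 1, which was B4galnt2. Fold changes of transgenic mdx against mdx had an r of -0.211 with those of AAV-Galgt2 against PBS, -0.055 without PBS replicate 1 and -0.124 without mdx replicate 2. Laminin, agrin and integrin genes (-0.26) and matrix genes (-0.19) were lower in transgenic mdx against mdx (camera, adjusted p = 0.0388 for both, and 0.344 and 0.605 with an estimated correlation). Without mdx replicate 1 these medians were -0.16 and -0.15, and neither list was called without that array or without transgenic mdx replicate 2. The laminin, agrin and integrin list also had no call without either PBS array. Endothelial genes had -0.94 in transgenic mdx against mdx and 0.38 in AAV-Galgt2 against PBS (camera, adjusted p = 0.00187, and 0.185 with an estimated correlation). The latter had no call without PBS replicate 2.

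**Figure D3:**
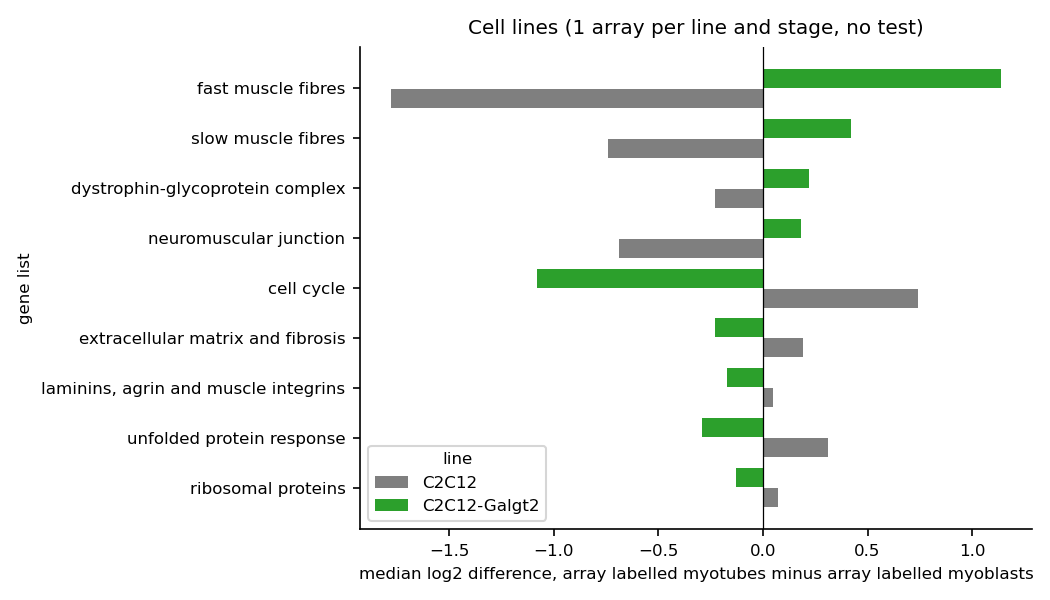
Median log2 difference of 9 gene lists between the array labelled myotubes and the array labelled myoblasts, for C2C12 (grey) and C2C12-Galgt2 (green); each bar compares 1 array with 1 array and carries no test. Fast fibre genes have a median of -1.78 in C2C12 and 1.14 in C2C12-Galgt2.

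In the cell lines, muscle genes of the C2C12-Galgt2 pair were higher in the array labelled myotubes, and those of the untransfected C2C12 pair in the array labelled myoblasts. Myh4, a fast myosin, differed by 3.47 in the C2C12-Galgt2 pair and by -5.22 in the C2C12 pair, Myl2 by 7.31 and -4.72, and Dmd (at its brightest probe set in the cells, another than in muscle) by 4.31 and -2.77, labelled myotubes minus labelled myoblasts with 1 array each. Of 16 fast fibre genes 9 were at least 2-fold higher in the C2C12-Galgt2 pair (median 1.14), and 11 at least 2-fold lower in the C2C12 pair (median -1.78). Cell cycle genes had medians of -1.08 and 0.74. At least 2-fold differences pointed the same way in both lines for 77 genes and opposite ways for 459, and no test was run, with 1 array per condition. Pclo (3.20 in C2C12 and 3.44 in C2C12-Galgt2) and Vegfc (-2.22 and -2.62), a growth factor for lymphatic vessels, were among the 77.

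Against untransfected C2C12 the C2C12-Galgt2 line had higher Mycn, a proto-oncogene, by 8.02 in the arrays labelled myoblasts and 9.02 in those labelled myotubes, higher B4galnt2 by 5.18 and 6.01, and higher Serpinb2 by 3.77 and 3.43. Mfsd6 (-2.09 and -5.10), Itga4 (-1.45 and -5.50), an integrin subunit, and E2f7 (-1.44 and -3.69) were lower at both labelled stages. Cell cycle genes had medians of -0.30 and -2.42 as labelled, and of -1.09 and -1.66 when each C2C12-Galgt2 array was set against the other C2C12 array. The count of genes at least 2-fold different the same way at both stages was 107, and 228 with the C2C12 labels exchanged, a setting chosen after seeing the data.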

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

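The tests that weigh explanations here were chosen only after the results were seen, and the conditions under which the array exchange, lymphocyte, fibre, carrier and mixture tests decide were changed after their first values.

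Myotubes and myoblasts differed in opposite ways in both cell lines: 459 genes were at least 2-fold different in one direction in C2C12 and in the other in C2C12-Galgt2, a difference that was not tested, with 1 array per condition. An exchange between an untransfected and a transfected array is argued against by B4galnt2, with an intensity of 23.85 and 27.97 in the untransfected and 864.2 and 1802 in the transfected arrays. The pair that runs against its labels, with a fast fibre median of -1.78, is the untransfected one, and an effect of Galgt2 on differentiation was not tested. The labelled C2C12 myoblasts correlated at 0.9899 with C2C12-Galgt2 myotubes and at 0.9785 with C2C12-Galgt2 myoblasts. An exchange of the labels of both untransfected arrays, and cultures that did not follow their labelled stage, stay open and no test here separates them.

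Macrophage genes responded differently to the transgene in mdx and in normal muscle, with a median interaction of -1.96 (camera, adjusted p = 8.82e-25, and adjusted p = 0.153 with an estimated correlation) and a median of -1.20 in transgenic mdx against mdx. Their median in mdx against wild type was 2.47, from mdx and wild-type arrays that enter the interaction with opposite signs. The part of these shared arrays was not separated, for this list or for the other interaction lists below. A single mdx array is argued against by the weaker of both medians with 1 mdx array left out, -0.79 without mdx replicate 1. A lower share of all white blood cells could not be excluded. The lymphocyte median was 0.03, but 2 of the 16 lymphocyte genes lay above the median level of mdx muscle. A subset of 6 genes picked after their values were seen, at least 2-fold above wild type in mdx, gave -0.01. Neutrophil and mast cell genes had -0.74 with 9 of 13 negative (camera, adjusted p = 0.176). Antigen presentation genes had -0.56 with 10 of 11 negative (camera, adjusted p = 0.00339, and 0.344 with an estimated correlation). Of the 32 macrophage genes 20 lay above the median level in wild-type muscle and 0 were shared with other lists, and the abundant Lgals3 had log2 levels of 12.49 and 12.46 in mdx and 10.91 and 11.05 in transgenic mdx. Fewer macrophages, less transcript per macrophage and the substrain of the mice, C57BL/10J for mdx and a cross with C57BL/6J for transgenic mdx, stay open and were not tested.

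Dmd was higher in transgenic mdx than in mdx muscle by 1.54 ± 0.20 on the log2 scale. A larger share of muscle fibre RNA as the whole source is argued against by 26 fibre genes with room below the highest array value for a rise as large as that of Dmd, whose median was 0.26 with a standard deviation of 0.80, although 2 of them had values at or above that of Dmd, slow fibre genes had a median of 0.78, and fast fibre genes (-0.14) lay too close to the highest array value to tell. For RNA of a female carrier in 1 array the 4 Dmd probe sets disagree (median 0.61, array with Xist signal minus the other). At the 2 brighter ones (wild-type log2 11.15 and 11.08) these arrays differed by -0.02 and 0.40. There the array without Xist signal exceeded the higher mdx array by 1.35 and 0.74, which argues against a carrier as the whole source at these probe sets. At the 2 dimmer ones (6.6 and 6.56) the array with Xist signal was higher by 0.83 and 1.63. The array without it differed from the higher mdx array by -1.35 and -0.15 there, so the dimmer probe sets showed no rise in that array and a carrier stays open. That array, transgenic mdx replicate 2, had the highest Gapdh and Actb 3' to 5' probe set ratios of its array set (log2 1.23 and 2.05). Whether its RNA quality lowered the dimmer probe sets was not tested. RNA of dystrophin-positive transgenic muscle mixed into both arrays would need 33.3% of the transgenic level, or -1.59 on the log2 scale, and 0 genes lay below that share at an adjusted p under 0.05, in a test with almost no power, since limma called 1 gene lower in transgenic mdx than in transgenic muscle. More dystrophin transcript in mdx muscle with the transgene, and the genetic background of the cross, stay open and were not tested.

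Genes with a different transgene response in mdx than in normal muscle by the interaction were Muc15 (3.21), AF067061 (2.67), Tcstv1 (2.47) and Kcnj3 (2.20), higher in mdx, and Lgals3 (-4.70), Cd84 (-3.13), Ms4a7 (-2.85) and Tyrobp (-2.82), lower in mdx. None of these 8 genes passed with every array left out in turn, and 0 genes passed without wild-type replicate 1 or 2.

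Other lists with an interaction were regeneration genes (-1.24, adjusted p = 3.34e-13, and adjusted p = 0.125 with an estimated correlation) and cell cycle genes (-1.48, adjusted p = 3.74e-13, and adjusted p = 0.214 with an estimated correlation). Matrix genes (-0.88, adjusted p = 7.5e-12, and adjusted p = 0.158 with an estimated correlation) and antigen presentation genes (-1.04, adjusted p = 5.84e-09, and adjusted p = 0.125 with an estimated correlation) had negative medians too. So had laminin, agrin and integrin genes (-0.54, adjusted p = 2.54e-05, and adjusted p = 0.148 with an estimated correlation) and neuromuscular junction genes (-0.46, adjusted p = 9.04e-05, and adjusted p = 0.242 with an estimated correlation). Neutrophil and mast cell genes had -1.55 (adjusted p = 0.000115, and adjusted p = 0.242 with an estimated correlation), -0.72 without transgenic replicate 1 and -2.38 without transgenic replicate 2. Endothelial genes had -0.44 (adjusted p = 0.014, and adjusted p = 0.225 with an estimated correlation), with no call without replicate 1 of wild type (-0.40) or mdx (-0.45), and medians of -0.78 without wild-type replicate 2 and -0.70 without mdx replicate 2. Skin genes had 0.21 (adjusted p = 0.0289, and adjusted p = 0.242 with an estimated correlation), with no call without replicate 1 of wild type (0.38), mdx (0.15), transgenic (0.32) or transgenic mdx (0.08), and 0.37, 0.46 and 0.51 without replicate 2 of wild type, transgenic and transgenic mdx.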

How the results depend on the processing

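Leaving out mdx replicate 2 together with transgenic mdx replicate 1, the exchange of the C2C12 labels, and the list alternatives for transgenic mdx against wild type and for the interaction were tests chosen only after seeing the data. Of 268 named called values none reversed in any setting run, and 64 lost their call within the array set alone, 66 with the replicate block, 26 with the mean of probe sets, 14 with shifted medians, 12 with quantile normalization, 10 with a trend, 2 of 254 without the lowest 1 in 3 of genes, 105 without wild-type replicate 1 and 108 without wild-type replicate 2. Outside the interaction, the largest rises and falls were named only where replicate values do not overlap between the groups. Leaving out 1 array could therefore not reverse them. Of 86 called lists 0 to 12 lost their call under the same alternatives, and 86 with an estimated correlation, which left 0 called in each of the 6 comparisons. These counts are per setting. Apart from the estimated correlation, the named values and lists that lost a call differed between settings. More of them therefore lost it in at least 1 setting than in any single one. For mdx against wild type, with 990 genes called, the replicate block gave 582, both arrays left out 431 and an adjusted p under 0.10 1850, and leaving out 1 array gave 132 to 1338. For transgenic against wild type, with 573, the array set alone gave 365, an adjusted p under 0.10 881 and leaving out 1 array 184 to 653. For transgenic mdx against mdx, with 1107, the array set alone gave 643, the block 677, both arrays left out 371, an adjusted p under 0.10 2001 and leaving out 1 array 311 to 1290. For transgenic mdx against wild type, with 1324, the array set alone gave 842, an adjusted p under 0.10 2167 and leaving out 1 array 434 to 1575. The interaction, with 8, had 0 with the block, 16 with quantile normalization, 15 with shifted medians, 4 without the lowest 1 in 3 of genes, 5 with the mean of probe sets, 20 with a trend, 1 with both arrays left out, 25 at an adjusted p under 0.10 and 0 to 142 with 1 array left out. AAV-Galgt2 against PBS, with 0, had 0 to 158 with 1 array left out, and 11 called lists with quantile normalization in place of 17. Its cell cycle median of 0.31 reversed to -0.20 without PBS replicate 1 and was 0.85 without PBS replicate 2. The correlation of fold changes of mdx against wild type and AAV-Galgt2 against PBS, 0.274, ran from -0.033 without PBS replicate 1 to 0.407 without PBS replicate 2, and that of transgenic mdx against mdx and AAV-Galgt2 against PBS, -0.211, from -0.263 to -0.055. That of both transgene effects, 0.391, was 0.265 as Spearman rho and 0.325 to 0.393 with 1 array left out. In the cell lines 77 genes differed the same way between stages in both lines, 45 with the mean of probe sets and 258 at 1.5-fold. With the C2C12 labels exchanged the count was 459. That exchange turns the sign of the C2C12 difference, so it counts the genes of opposite directions again by construction. The 107 that differed between lines at both stages were 68 with the mean of probe sets, 387 at 1.5-fold and 228 with the labels exchanged. Looser thresholds also call more genes by construction, and fewer arrays leave less to estimate the variance from. For the remaining changes the cause was not tested. With 1 array of a group left out, the lone sample is assumed to vary like the other groups. The labels do not say whether replicate numbers pair the samples. Deviations of replicates correlated at -0.44 (wild type with mdx) to 0.54 (wild type with transgenic) between groups of the transgenic set. The value was -0.05 between AAV-Galgt2 and PBS. With 2 arrays per group these values cannot settle whether samples are paired or share a batch. The block leaves 4 residual degrees of freedom in place of 6, so a call lost with it need not mean a smaller effect. No detection calls were used here, so for dim genes a low value is not separated from background, and small changes in them were not detectable.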

Other observations

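The test of the unfolded protein response in AAV-Galgt2 muscle as an explanation was chosen only after its result was seen.

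Muscle of mdx mice differed from wild type in further lists. The acetylcholine receptor genes Chrna1 (2.17 ± 0.38) and Chrng (1.79 ± 0.34) were the 2 of 16 neuromuscular junction genes that rose, 2 also over the list alone. The junction median was 0.56 (adjusted p = 0.000359, and adjusted p = 0.305 with an estimated correlation), and 0.35 without mdx replicate 2. Chrna1 had no call without either wild-type array or mdx replicate 2, and Chrng none without wild-type replicate 1 or mdx replicate 2. Of the lymphocyte genes Cd3e (2.47 ± 0.55) and Gzma (1.83 ± 0.39) rose, 2 of 16 and 3 over the list alone. The lymphocyte median was 0.82 (adjusted p = 0.000292, and adjusted p = 0.362 with an estimated correlation), 0.39 without mdx replicate 1 (adjusted p = 0.172) and 1.66 without mdx replicate 2. Cd3e and Gzma had no call without either wild-type array or mdx replicate 1, and Cd3e none without either AAV-Galgt2 array. Among laminin, agrin and integrin genes Itga5 (1.54 ± 0.25) rose, 1 of 18 and 3 over the list alone, and not without wild-type replicate 2. Their median was 0.44 (adjusted p = 0.00117, and adjusted p = 0.153 with an estimated correlation), and 0.26 without mdx replicate 1 (adjusted p = 0.122). Of 15 clock genes Hlf (-1.97 ± 0.31) fell, 4 over the list alone, and Hlf not without either wild-type array. The clock median was -0.62 (adjusted p = 0.00366, and adjusted p = 0.153 with an estimated correlation), and -0.14 without mdx replicate 2 (adjusted p = 0.103).

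The glycosyltransferase B4galnt1 rose by 2.44 ± 0.32 in mdx muscle, with each array left out too, in a list with no call (median 0.33, adjusted p = 0.131). Ribosomal protein genes had a median of 0.23 in mdx (adjusted p = 0.0332, and adjusted p = 0.153 with an estimated correlation), with no call without wild-type replicate 2 (0.27), mdx replicate 1 (0.24) or either PBS array (0.23). Lists with no call in mdx muscle included the dystrophin-glycoprotein complex (-0.18, adjusted p = 0.112), lipid use (0.03, adjusted p = 0.957), fat cells (0.42, adjusted p = 0.153), Schwann cells (-0.04, adjusted p = 0.781) and red blood cells (-0.04, adjusted p = 0.924).

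In transgenic against wild-type muscle the stress genes Mt2 (2.86 ± 0.42) and Cdkn1a (2.80 ± 0.30) rose, with 3 of 17 atrophy genes passing and 5 over the list alone. The atrophy median was 0.42 (adjusted p = 0.00144, and adjusted p = 0.124 with an estimated correlation), and 0.12 without wild-type replicate 2 or without transgenic replicate 1. Oxidative phosphorylation genes were negative in 27 of 27 cases with 0 passing, median -0.20 (adjusted p = 0.0134, and adjusted p = 0.404 with an estimated correlation), and had no call without transgenic replicate 1 (-0.18, adjusted p = 0.0624). Neutrophil and mast cell genes had a median of 0.81 (adjusted p = 0.00245, and adjusted p = 0.328 with an estimated correlation), 0.27 without transgenic replicate 1 (adjusted p = 0.162) and 1.64 without transgenic replicate 2. In transgenic mdx against mdx, glycolysis genes had a median of -0.36 (adjusted p = 0.00084, and adjusted p = 0.344 with an estimated correlation), -0.62 without transgenic mdx replicate 2 and -0.31 without mdx replicate 2.

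In AAV-Galgt2 against PBS muscle, smooth muscle genes had a median of 0.44 (adjusted p = 0.00621, and adjusted p = 0.216 with an estimated correlation), and 0.24 without AAV-Galgt2 replicate 1. Immediate early and heat shock genes had 0.49 (adjusted p = 0.00755, and adjusted p = 0.448 with an estimated correlation), with no call without AAV-Galgt2 replicate 2 (0.33) or PBS replicate 1 (0.28), and 0.75 without PBS replicate 2. Calpain and calcium genes had 0.30 (adjusted p = 0.00938, and adjusted p = 0.293 with an estimated correlation), with no call without PBS replicate 1 (0.19), and 0.58 without PBS replicate 2.

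Unfolded protein response genes rose in 7 of 20 cases in transgenic against wild type (adjusted p = 0.124 with an estimated correlation) and in 8 of 20 in transgenic mdx against mdx (adjusted p = 0.344 with an estimated correlation), and a hypothesis is that any large rise of B4galnt2 raises these genes in mdx muscle. In that form it is argued against by AAV-Galgt2 muscle, where their median was 0.02 (adjusted p = 0.769) while B4galnt2 was higher by 5.78. The AAV level of B4galnt2 was below the transgenic one, on another scale, and an effect that needs a higher level was not tested. In the cell lines the unfolded protein response median of C2C12-Galgt2 against C2C12 was 0.58 in labelled myoblasts and -0.07 in labelled myotubes. With each C2C12-Galgt2 array set against the other C2C12 array it was 0.28 for C2C12-Galgt2 myoblasts and 0.13 for C2C12-Galgt2 myotubes, so the direction at the myotube stage turned.

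Replicate 1 of transgenic mdx muscle had an Xist intensity of 633.1 and replicate 2 had 34.56, in mice labelled male. B4galnt2 had an intensity of 219.5 in mdx replicate 2. The 3' to 5' probe set ratio of Actb was 2.05 on the log2 scale in transgenic mdx replicate 2.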
